A study of Bos grunniens with 9 samples.

How the data were processed

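RNA sequencing libraries were made from testis tissue of 9 male yaks (Bos grunniens), with 3 animals at 6 months (6M), 3 at 18 months (18M) and 3 at 4 years (4Y). The labels call these stages juvenile, pubertal and sexually mature. Each library is a different animal, so the spread within a group is between animals. Cattle-yak hybrids are also named in the labels' protocols and were not analysed here.

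The authors deposited FPKM values (fragments scaled by transcript length and by the fragments mapped in a library) per isoform, rounded to 2 decimals, in a table of 144699 isoforms of 34330 gene IDs. RSEM and FastQC are named in the submitters' processing notes without a version. The aligner, the assembler and the genome build are not given in the sources used here. Of the isoforms, 49935 carry an Ensembl transcript ID, 79940 are further isoforms of Ensembl genes and 14824 belong to 7406 genes added to the annotation. In 2 further tables the authors deposited their own comparisons per isoform, 18M against 6M and 4Y against 18M. Per the file headers these hold a normalized mean signal of each age, a log2 fold change with its standard error, and a p-value with its adjusted value. The test behind them is not given in the sources used here.

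From these files the value of a gene was the sum of FPKM over the isoforms with the same gene name, or over the same gene ID where no name was given. Gene names came from the table for 16123 gene IDs, from its UniProt match for 1235 more and from its protein description for 20. Of the genes tested, 12983 had a symbol and 8663 had none, and 17 tested names summed several gene IDs, among them families of small RNAs, whose values are uncertain. Genes and isoforms with at least 1 FPKM in at least 3 libraries were tested, which left 21646 genes and 63906 isoforms. Values were analysed as log2(FPKM + 1), and a fold change on this scale understates the change of low genes. Because FPKM values are not counts, no count model was used, and tests that need counts were not run.

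Group means were compared with limma (version 3.58.1 in R 4.3.3; moderated test with an intensity trend, all 9 libraries in one fit, Benjamini-Hochberg adjusted p below 0.05). Adjusted p-values of genes and isoforms below come from this fit. Unequal change of the isoforms of a gene was tested with limma's diffSplice (Simes p per gene) in the 12670 genes with at least 2 tested isoforms. A switch was called where, in addition, the isoform with the highest mean differed between the ages. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with fry as another test. Results of fry are those of its directional test unless its mixed test, which ignores the direction of change, is named. Lists with fewer than 3 tested genes (red blood cells, epididymis and rete testis, mitochondrial genome) had no list test. PRM1, LDHC, DDX4, CCNB1, SPAG6 and AMH were not matched and were not analysed here. The named genes were fixed by a rule before the data were examined. These were the 3 largest rises and falls among called genes with a symbol, a mean of at least 5 FPKM in the higher group and no overlap between the groups, and from each list the 2 called members with the smallest adjusted p. Where fewer than 2 members of a main list were called, those with the highest mean FPKM made up the 2. For isoforms the 3 switches with the smallest p were named. One gene that this rule names is not reported here.

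The steps were tested on simulated data. For 18M against 6M over 21646 genes, the gene test recovered 20.0% of genes changed by 1 log2 unit, 66.0% at 2, 92.0% at 3 and 98.0% at 4, and 4.83% of its calls were false. For 4Y against 18M it recovered 20.0%, 60.0%, 92.0% and 94.0%, with 3.62% false, and for 4Y against 6M 16.0%, 60.0%, 90.0% and 100%, with 2.92% false. These simulations, also those of isoform usage, gave a feature the same spread in every library and drew features independently. The simulations of unchanged groups for the overlap of both steps used a gene's spread within each age instead. In the deposited values the 18M animals were less alike than those of the other ages, and 18M animal 2 deviated over many genes together. The recovered and false shares therefore need not hold for comparisons with 18M. In the isoform usage test over 12670 genes, diffSplice recovered 87.5% of 200 genes in which 1 isoform was changed by 3 log2 units for 18M against 6M, but 39.9% of its calls were false. For 4Y against 18M these shares were 89.0% and 37.8%. After that result a pair of other tests was tried on the simulated and the deposited values. The first, on the arcsine of isoform shares, recovered 0 of the 200 simulated genes in either comparison (11958 genes for 18M against 6M and 11940 for 4Y against 18M). The second, which gives each isoform its own spread, recovered 63.0% with 5.97% false calls for 18M against 6M, and 71.0% with 4.05% false calls for 4Y against 18M. The planned diffSplice counts are therefore given beside those of the own-spread test, and the counts of the arcsine test stand in the closing section.

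Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, median-ratio scaling, quantile normalization, a fit of the 6 libraries compared, a log2 fold of at least 1, no variance trend, a robust variance, sample weights, the highest isoform per gene, the replicate number as a block, and each library left out in turn. Every leave-out was planned, but the counts of called list members without 18M animal 2 were chosen after its correlations were seen. Sequencing depth is not stated. The relative depth estimated from the steps between low FPKM values, against 6M animal 1, was 100% to 110% at 6M, 119% to 131% at 18M and 83.2% to 86.5% at 4Y. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1).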

Results

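The yak testis was profiled at 3 ages, with 3 animals each, to map its transcriptome from the juvenile stage (6M) through puberty (18M) to sexual maturity (4Y). In the 6M libraries 14892 to 15418 genes reached 1 FPKM, against 18840 to 19264 at 18M and 19588 to 20095 at 4Y. The 10 most abundant genes held 11.97% to 12.7% of all FPKM at 6M, 6.59% to 9.09% at 18M and 5.68% to 5.98% at 4Y.

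Across the tested genes, libraries correlated within 6M at Pearson's r of 0.971 to 0.979 and within 4Y at 0.972 to 0.974; these are correlations across genes, which are not independent replicates. The 18M animals were less alike. Animals 1 and 3 correlated at 0.950, whereas animal 2 correlated with them at 0.866 and 0.835 and with the 4Y animals at 0.932 to 0.934. In 18M animal 2 the round spermatid list stood at 2.51 log2 units over its mean of the 9 libraries, against 1.18 and 0.715 in 18M animals 1 and 3 and 2.41 to 2.50 at 4Y. The Sertoli list stood there at -0.942, against 0.426 and 0.749 in animals 1 and 3, the Leydig list at -1.21, against 0.142 and -0.262, and the matrix list at -1.50, against -0.171 and 0.224.

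**Figure D1:**
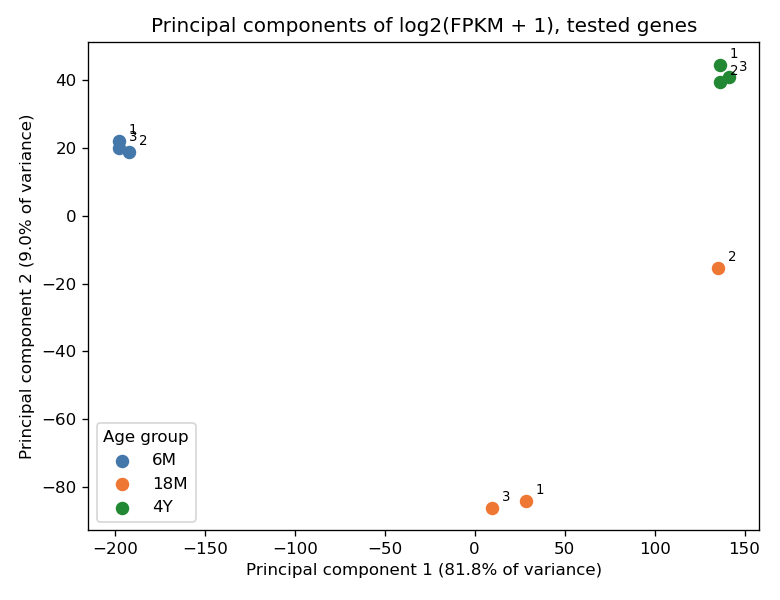
Principal components 1 (x axis, 81.8% of variance) and 2 (y axis, 9.03% of variance) of log2(FPKM + 1) over the tested genes; each point is 1 library, coloured by age and numbered by animal. On component 1 the 18M animal 2 (135) lies beside the 4Y animals (136 to 141), while 18M animals 1 and 3 lie at 28.3 and 9.88.

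The comparison of 18M with 6M asks what changes in the testis as puberty sets in. Genes of meiotic and haploid germ cells rose. All 27 tested genes of the elongating spermatid list rose (median log2 fold change 6.06; camera adjusted p = 2.6e-11), as did all 30 genes of the round spermatid and acrosome list (5.53; 2.6e-11) and all 34 of the axoneme and flagellum list (3.84; 1.05e-11). Of 28 genes of meiosis 27 rose (4.13; 4.11e-10). For these lists the adjusted p was 0.335 with an estimated correlation. Their counts were the same when adjusted over the list alone, and without 18M animal 2.

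TNP1 (ENSBGRG00000002189), a transition protein that replaces histones in spermatids, had the largest rise, from 0.0667 ± 0.115 FPKM at 6M to 3162 ± 2954 at 18M (SD, n = 3 each), a log2 fold change of 11.14 ± 0.50 (SE; adjusted p = 4.22e-07). Its 18M values were 1329, 6570 and 1588 FPKM in animals 1, 2 and 3. PHF7, a histone ubiquitin ligase of spermatids, rose from 1.51 ± 0.270 to 803 ± 355 FPKM (adjusted p = 1.45e-07). The sperm surface protein gene ADAM2 rose from 0.0767 ± 0.133 to 105 ± 39.5 FPKM, and ZPBP, an acrosomal protein gene, from 2.59 ± 0.578 to 187 ± 66.1 FPKM. Among flagellar genes, DRC3 of the dynein regulatory complex rose by 6.05 ± 0.24 log2 units and the dynein heavy chain DNAH17 by 5.66 ± 0.24. SYCE2, a part of the synaptonemal complex, rose from 2.01 ± 0.259 to 95.9 ± 9.79 FPKM. PIWIL1, which binds piRNAs in meiotic cells, rose from 0.26 ± 0.155 to 105 ± 26.7 FPKM. Of 17 tested piRNA pathway genes 15 rose (median 4.57; camera adjusted p = 1.53e-06; adjusted p = 0.335 with an estimated correlation), TDRD5 among them at 5.76 ± 0.21.

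The germ cell paralogs of metabolic enzymes followed the same direction, with 12 of 13 called higher (median 5.63; camera adjusted p = 8.11e-06; adjusted p = 0.335 with an estimated correlation). PGK2, a glycolytic kinase of spermatids, rose from 0.313 ± 0.0907 to 282 ± 141 FPKM and the glycerol kinase GK2 from 0.13 ± 0.0917 to 213 ± 137 FPKM. All 12 genes of ubiquitin and sperm protein turnover rose (median 4.57; camera adjusted p = 1.84e-05; adjusted p = 0.335 with an estimated correlation), with RNF151 at 7.07 ± 0.42 and UBE2U at 5.13 ± 0.32 log2 units. The counts of both lists were the same when adjusted over the list alone.

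Spermatogonial genes moved less uniformly. In the differentiating list 7 of 9 genes rose and 1 fell (median 1.67; camera adjusted p = 0.047; adjusted p = 0.385 with an estimated correlation), with the same counts adjusted over the list alone. This call ended under 12 of the alternatives, with an adjusted p of up to 0.07 over the leave-outs (6M animal 3 and each 18M and 4Y animal). DMRTB1, a regulator of the step from mitosis to meiosis, rose from 0.51 ± 0.261 to 50.3 ± 4.13 FPKM, and SOHLH2 from 1.36 ± 1.37 to 45.2 ± 2.01 FPKM. Of 12 genes of undifferentiated spermatogonia 3 rose and 1 fell, or 2 and 1 adjusted over the list alone and 6 and 1 without 18M animal 2. The median of this list was 0.31 but -0.47 after quantile normalization, and neither camera, which gave it as lower than other genes (adjusted p = 0.797), nor fry, which gave it as up (adjusted p = 0.246), called it. NANOS3 rose from 1.28 ± 0.508 to 16.2 ± 4.19 FPKM and ID4 from 2.89 ± 1.28 to 35.9 ± 20.1 FPKM. Among 23 cell cycle genes 16 rose and 2 fell, with the same counts adjusted over the list alone (median 1.39; camera adjusted p = 0.0126; adjusted p = 0.435 with an estimated correlation). CDC20 rose by 4.19 ± 0.27 and CCNB2 by 3.99 ± 0.25 log2 units.

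Most Leydig cell and matrix genes tested fell. Of 14 Leydig cell genes 10 fell (median -1.70; camera adjusted p = 2.67e-06; adjusted p = 0.335 with an estimated correlation). STAR, which brings cholesterol into mitochondria for steroid synthesis, fell from 512 ± 38.7 to 26.7 ± 10.7 FPKM (adjusted p = 5.31e-06), and CYP11A1, the enzyme that cleaves the cholesterol side chain, from 184 ± 23.4 to 11.1 ± 5.58 FPKM. In the extracellular matrix list 22 of 31 genes fell and 1 rose (median -1.80; camera adjusted p = 2e-10; adjusted p = 0.335 with an estimated correlation). LUM fell from 144 ± 44.6 to 1.83 ± 1.10 FPKM and COL4A2, a basement membrane collagen, from 452 ± 92.1 to 24.3 ± 14.0 FPKM. Of 19 genes of cholesterol synthesis and uptake 12 fell and 1 rose (median -1.58; camera adjusted p = 7.39e-06; adjusted p = 0.335 with an estimated correlation), with NSDHL at -2.41 ± 0.30. The counts of these lists were the same when adjusted over the list alone. Without 18M animal 2 the Leydig median was -1.16 (10 lower, 1 higher) and the matrix median -1.39 (23 lower, 1 higher).

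Sertoli cell genes went both ways, with 10 of 20 lower and 4 higher, also adjusted over the list alone. The median was -0.97 (camera adjusted p = 0.00763; 0.241 after quantile normalization; adjusted p = 0.533 with an estimated correlation), whereas fry gave the direction as up (adjusted p = 0.791). Without 18M animal 2 the median was -0.59, with 10 lower and 6 higher. ESPN rose from 2.46 ± 0.197 to 103 ± 18.1 FPKM and the defensin gene DEFB119 from 0.04 ± 0.0361 to 43.7 ± 20.3 FPKM. In the blood-testis barrier list 4 of 15 genes rose and 4 fell, or 4 and 5 adjusted over the list alone (median -0.55; camera adjusted p = 0.0306; adjusted p = 0.435 with an estimated correlation). Its call ended after quantile normalization (adjusted p = 0.14) and without 18M animal 2 (0.0531; median -0.11). JAM3 rose by 1.53 ± 0.16 and CLDN1 was at -2.58 ± 0.28 log2 units. Of 13 myoid and smooth muscle genes 3 fell and 2 rose, or 3 and 0 adjusted over the list alone (median -0.003, and 0.39 without 18M animal 2; camera adjusted p = 0.0774). Camera called this list lower without 6M animal 1 (0.044) or 2 (0.0434) and without 18M animal 1 (0.0373) or 3 (0.0479). CALD1 fell from 114 ± 37.6 to 29.5 ± 17.3 FPKM and MYLK from 62.8 ± 9.72 to 26.3 ± 11.6 FPKM.

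Among the lists of other cells and of RNA state, 6 of 12 endothelial genes fell and 1 rose (median -1.13; camera adjusted p = 0.00193; adjusted p = 0.385 with an estimated correlation). Without 18M animal 2 the median was -0.58 (5 lower, 1 higher; camera adjusted p = 0.00404). EMCN was at -2.05 ± 0.33 and VWF, also of endothelium, at 2.17 ± 0.31. Of 15 leukocyte genes 3 rose (median -0.46, mean 0.04, and median 0.23 without 18M animal 2; camera adjusted p = 0.172), CD14 by 4.04 ± 0.41 and AIF1 by 2.35 ± 0.48. CD14 was at 31.1, 74.85 and 19.29 FPKM and AIF1 at 99.86, 297.81 and 76.09 FPKM in 18M animals 1 to 3. Both were highest in animal 2, where the leukocyte list stood at -1.06, against 0.737 and 1.02 in animals 1 and 3. They thus did not follow their list among the 18M animals. These endothelial and leukocyte counts were the same adjusted over the list alone. Of 16 hypoxia genes 4 rose and 6 fell, also adjusted over the list alone, and 6 and 6 without 18M animal 2 (median -0.33, mean 0.08, fry up; camera adjusted p = 0.075), with CA9 at 5.78 ± 0.23 and EGLN2 at 2.64 ± 0.24. Of 14 immediate early and heat shock genes 2 rose and 3 fell, or 1 and 1 adjusted over the list alone (median -0.28, and 0.24 without 18M animal 2; camera adjusted p = 0.0843, but 0.047 with a median of -0.70 without 18M animal 3), with DNAJB1 at 3.08 ± 0.26 and HSPA8 at -1.47 ± 0.38. Ribosomal protein genes fell, 36 of 38, also adjusted over the list alone (median -1.90, and -0.74 after quantile normalization; camera adjusted p = 8.97e-18; adjusted p = 0.335 with an estimated correlation), with RPL7 from 4399 ± 404 to 913 ± 241 FPKM and RPL6 from 3392 ± 397 to 487 ± 185 FPKM. Of the lists with too few genes for a test, HBA of red blood cells was at 0.85 ± 0.28 (adjusted p = 0.0267), but at -0.11 after quantile normalization, and its call ended without 6M animal 2 or 3 and without 18M animal 1 or 3 (adjusted p up to 0.0905). The mitochondrial ND6 was at -1.58 ± 0.30 (adjusted p = 0.00172), a call that ended after quantile normalization. The 1 gene tested for epididymis and rete testis, at -1.32, was not called, but was lower adjusted over the list alone.

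The largest falls were of CHGA (ENSBGRG00000020399), a protein of secretory granules, from 718 ± 292 to 7.72 ± 5.53 FPKM (log2 fold change -6.61 ± 0.59, adjusted p = 1.61e-05), TINAGL1 (ENSBGRG00000008317), from 337 ± 71.4 to 3.38 ± 2.75 FPKM (-6.52 ± 0.48), and PLA2G1B (ENSBGRG00000026299), a secreted phospholipase, from 2600 ± 683 to 52.3 ± 46.7 FPKM (-6.38 ± 0.91). Over the leave-outs these ranged from -7.02 to -5.83 for CHGA, -6.98 to -5.86 for TINAGL1 and -7.22 to -5.10 for PLA2G1B, each nearest 0 without 18M animal 2. PLA2G1B was at 97.41, 4.19 and 55.35 FPKM in 18M animals 1 to 3. The thymosin genes TMSB4X and TMSB10 were the other 2 genes named as largest rises, but both are listed at 0 in all 3 of the 6M libraries. At 18M, TMSB4X was at 979.97, 217.53 and 1448 FPKM and TMSB10 at 979.97, 217.53 and 663.68 FPKM in animals 1 to 3. The identical values in animals 1 and 2 and the near-identical copies of thymosin genes leave both uncertain.

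In all, 12259 of 21646 genes changed between 6M and 18M, 8653 higher and 3606 lower. The higher share was 70.6% of calls, 58.6% after median-ratio scaling and 41.6% after quantile normalization. The median log2 fold change of all genes was 0.49, 0.28 and -0.18 in turn, and camera sets a list against the other genes, so relative to this median. Of 21 lists tested, camera called 16, and 0 with an estimated correlation (the lowest adjusted p was 0.335). Of these 16, fry did not call the Sertoli (adjusted p = 0.791), barrier (0.36) and endothelial (0.0573) lists. Its mixed test called each of them (adjusted p = 1.8e-09, 2.81e-05 and 0.000257 in turn).

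**Figure D2:**
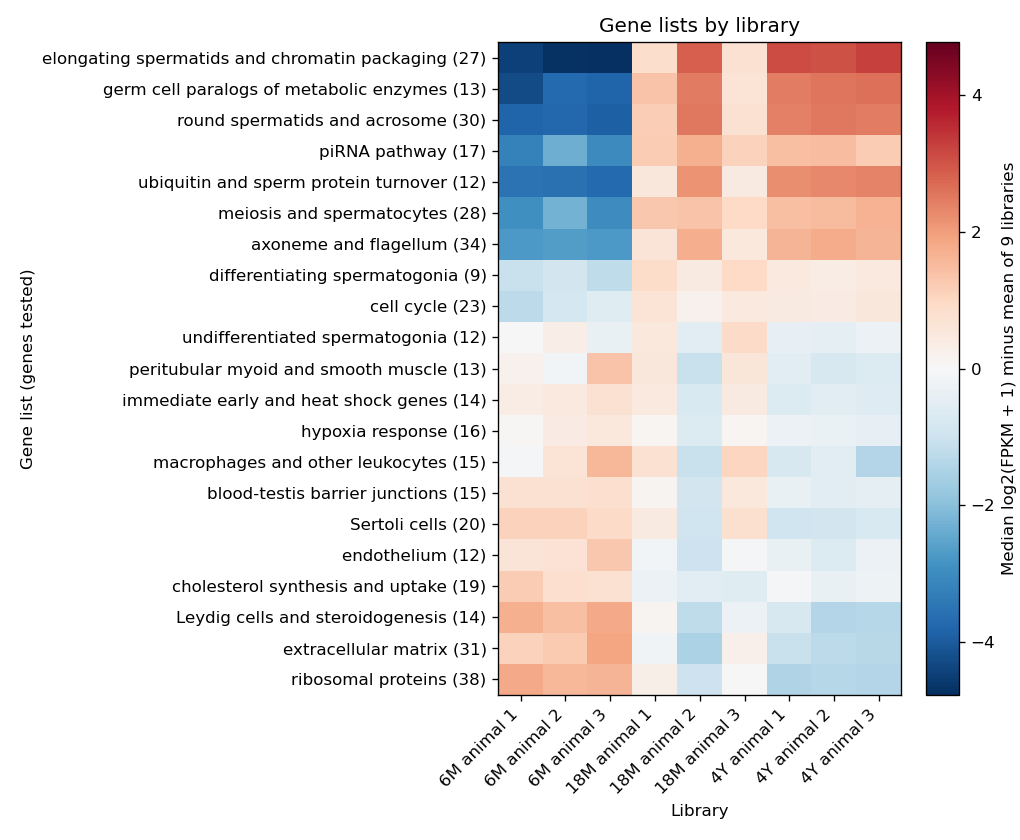
Level of each gene list (y axis, with the number of tested genes) in each library (x axis), as the median over its genes of log2(FPKM + 1) minus the gene's mean of the 9 libraries (colour). The elongating spermatid list goes from -4.78 to -4.45 at 6M to 3.06 to 3.26 at 4Y, and 18M animal 2 (2.84) stands above 18M animals 1 and 3 (0.826 and 0.727).

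The comparison of 4Y with 18M covers the step from puberty to sexual maturity. Camera placed the spermatid lists higher and the Sertoli, matrix and ribosomal protein lists lower than other genes, with a minority of the Sertoli and matrix members called. Because 18M animal 2 lay nearest the 4Y animals, leaving it out tends to widen this difference. Counts without it are therefore no independent support. Leaving out 18M animal 1 or 3 in its place kept 27.84% and 37.4% of the planned gene calls, against 99.9% without animal 2. Of 27 elongating spermatid genes 13 rose, 22 adjusted over the list alone and 26 without 18M animal 2 (median 1.39, ranging from 0.98 to 2.04 over the leave-outs; camera adjusted p = 1.21e-07). Of 30 round spermatid genes 9 rose, 15 adjusted over the list alone and 28 without 18M animal 2 (median 1.06, ranging from 0.69 to 1.71 over the leave-outs; camera adjusted p = 7.13e-06). AKAP4, an anchoring protein of the sperm fibrous sheath, rose from 31.8 ± 26.8 to 120 ± 7.02 FPKM (log2 fold change 2.19 ± 0.46, adjusted p = 0.0167) and ODF4 of the outer dense fibres from 30.8 ± 16.1 to 81.9 ± 0.996 FPKM. CREM, a transcription factor of spermatids, rose from 26.5 ± 13.9 to 81.1 ± 2.84 FPKM and GARIN1B from 33.4 ± 31.3 to 107 ± 9.14 FPKM. For all lists in this comparison the adjusted p was 0.755 or higher with an estimated correlation, and the directional test of fry called 0 of them (the lowest adjusted p was 0.203). Fry's mixed test called the meiosis (adjusted p = 1.55e-07), hypoxia (0.00774) and leukocyte (0.0173) lists. It also called the undifferentiated spermatogonia (0.0259), ribosomal protein (0.0259) and cholesterol (0.0332) lists.

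Of 34 axoneme genes 3 rose, 0 adjusted over the list alone and 24 without 18M animal 2 (median 0.67, ranging from 0.46 to 1.02 over the leave-outs; camera adjusted p = 9.2e-05). The sperm calcium channel genes CATSPER1 and CATSPER3 rose by 2.30 ± 0.57 and 1.66 ± 0.44 log2 units. Of 13 germ cell paralogs of metabolic enzymes 7 rose, also adjusted over the list alone (median 1.01; camera adjusted p = 0.0158), with ACSBG2 at 1.97 ± 0.49 and ENO4 at 1.12 ± 0.29; the list's call ended without 18M animal 3 (adjusted p = 0.0981). Of 12 genes of ubiquitin and sperm protein turnover 5 rose, 6 adjusted over the list alone and 11 without 18M animal 2 (median 0.91, ranging from 0.63 to 1.35; camera adjusted p = 0.00139), with UBQLNL at 2.15 ± 0.51 and UBE2J1 at 1.77 ± 0.43. Meiotic genes as a list were not called (median 0.09; camera adjusted p = 0.167, but 0.0482 with median-ratio scaling), with 1 of 28 higher and 1 lower, or 1 and 0 adjusted over the list alone and 8 and 1 without 18M animal 2. The lower gene was TEX12, from 18.8 ± 5.87 to 9.74 ± 1.17 FPKM (adjusted p = 0.0474), a call that ended under 15 of the alternatives. The higher gene was MEIOC, a meiotic regulator, which is listed at 0 in all 3 of the 18M libraries and was at 27.5, 28.4 and 22.7 FPKM in the 4Y animals. These values of 0 can be failed estimates, so the rise of MEIOC is uncertain.

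Of 12 genes of undifferentiated spermatogonia 3 fell, also adjusted over the list alone, and 8 without 18M animal 2 (median -0.69, ranging from -1.02 to -0.44 over the leave-outs; camera adjusted p = 0.0123, and 0.103 without 18M animal 3). ID4 fell from 35.9 ± 20.1 to 4.04 ± 0.496 FPKM (log2 fold change -2.69 ± 0.44) and NANOS3 from 16.2 ± 4.19 to 5.66 ± 0.556 FPKM. In the differentiating list 1 of 9 fell, also adjusted over the list alone, against 4 lower and 1 higher without 18M animal 2 (median -0.06; camera adjusted p = 0.535). This was SOHLH1, from 63.4 ± 34.4 to 13.6 ± 2.27 FPKM, while DMRT1 was not called (-0.48 ± 0.34, adjusted p = 0.323). Of 23 cell cycle genes 1 rose and 0 adjusted over the list alone, against 3 higher and 6 lower without 18M animal 2 (median 0.07; camera adjusted p = 0.889). MKI67 rose from 8.01 ± 3.65 to 16.9 ± 3.56 FPKM and PCNA was not called (-0.06 ± 0.20, adjusted p = 0.839). Of 17 piRNA genes GTSF1 was higher at 1.26 ± 0.32 and PLD6 lower at -1.04 ± 0.24, with the same 2 calls adjusted over the list alone, against 3 higher and 2 lower without 18M animal 2 (camera adjusted p = 0.642).

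Of 20 Sertoli cell genes 5 fell, also adjusted over the list alone, and 14 without 18M animal 2 (median -0.55, ranging from -1.01 to -0.33 over the leave-outs; camera adjusted p = 0.0063, and 0.0932 without 18M animal 3). INHA, the alpha subunit of inhibin, fell from 696 ± 442 to 86.7 ± 19.3 FPKM and SOX9, a Sertoli transcription factor, from 18.7 ± 7.41 to 6.16 ± 0.710 FPKM. In the matrix list 5 of 31 genes fell, 4 adjusted over the list alone and 21 without 18M animal 2 (median -0.74, ranging from -1.20 to -0.49; camera adjusted p = 0.0063, and 0.0932 without 18M animal 3), with COL18A1 from 83.6 ± 56.4 to 8.52 ± 1.56 FPKM and LAMB2 from 45.1 ± 5.55 to 26.5 ± 1.90 FPKM. The Leydig list was not called (median -0.70, ranging from -0.97 to -0.38; camera adjusted p = 0.0877) and 1 of its 14 genes, NR5A1, fell (-1.25 ± 0.38), but 0 adjusted over the list alone. Without 18M animal 2, 8 Leydig genes fell and camera called the list (adjusted p = 0.0179), as it did without 4Y animal 1 (0.0245) and with a replicate block (0.0478). INSL3, a hormone of Leydig cells, was at 9589 ± 6784 FPKM at 18M and 3868 ± 811 at 4Y (adjusted p = 0.192). Of 13 myoid genes 0 were called by limma (median -0.77, ranging from -1.29 to -0.46; camera adjusted p = 0.0796, but 0.0377 with median-ratio scaling, 0.0457 without 6M animal 3, 0.049 with 6 libraries in the fit and 0.0372 with a replicate block), against 9 that fell and 1 that rose without 18M animal 2 (camera adjusted p = 0.00408), with TPM1 at -1.06 ± 0.44 (adjusted p = 0.106) and ACTA2 at -0.99 ± 0.89 (adjusted p = 0.426).

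The remaining lists were not called by camera. Without 18M animal 2 camera also called the immediate early and heat shock list (adjusted p = 0.0179). Of 15 barrier genes 1 rose (NECTIN3, 1.20 ± 0.31) and 2 fell, CLDN5 among them at -2.67 ± 0.59, or 1 and 3 adjusted over the list alone and 2 and 9 without 18M animal 2 (median -0.31, ranging from -0.75 to -0.05; camera adjusted p = 0.305). CLDN5 was also the 1 endothelial gene of 12 that fell, likewise adjusted over the list alone, against 4 lower and 1 higher without 18M animal 2 (camera adjusted p = 0.642). Of 19 cholesterol genes 1 rose (DHCR7, 0.99 ± 0.22), also adjusted over the list alone, against 6 higher and 3 lower without 18M animal 2 (camera adjusted p = 0.232). Of 16 hypoxia genes 5 fell, ADM at -1.44 ± 0.34 and VEGFA at -1.02 ± 0.27 among them, or 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.457). Of 15 leukocyte genes 2 rose and 3 fell, or 3 and 4 adjusted over the list alone and 2 and 9 without 18M animal 2 (median -1.09, and -1.88 without that animal; camera adjusted p = 0.178), with MRC1 at 1.87 ± 0.28 and PTPRC at -1.86 ± 0.50. Of 14 immediate early and heat shock genes 2 fell, also adjusted over the list alone, against 9 lower and 1 higher without 18M animal 2 (median -0.57, ranging from -1.06 to -0.29; camera adjusted p = 0.167), IER2 at -1.80 ± 0.47 and JUN at -1.77 ± 0.50. Ribosomal protein genes fell in contrast, 20 of 38, 26 adjusted over the list alone and 38 without 18M animal 2 (median -1.10, and -1.50 without that animal; camera adjusted p = 1.62e-10), with RPS15 from 2051 ± 790 to 403 ± 3.92 FPKM and RPL15 from 1816 ± 445 to 657 ± 56.8 FPKM. The mitochondrial ND6 was not called, but was lower without 18M animal 2 (-0.86).

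The largest falls were of P3H3 (ENSBGRG00000022465), a collagen prolyl hydroxylase, from 137 ± 92.1 to 1.84 ± 0.589 FPKM (log2 fold change -5.30 ± 0.54, adjusted p = 0.00111), the retinoic acid binding protein gene CRABP2 (ENSBGRG00000024907), from 66.6 ± 42.7 to 1.31 ± 0.975 FPKM, and INAFM1 (ENSBGRG00000014787), from 64.0 ± 40.4 to 1.70 ± 1.53 FPKM. The 3 genes named as largest rises are listed at 0 in all 3 of the 18M libraries. OST4, a subunit of the oligosaccharyltransferase that every cell uses, was at 88.7, 70.3 and 165 FPKM in the 4Y animals, the mitochondrial ribosomal gene MRPS33 at 50.3, 83.6 and 55.0, and the Y_RNA family at 97.3, 103 and 156. Such values of 0 can be failed estimates.

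In all, 4051 genes changed between 18M and 4Y, 1980 higher and 2071 lower. Genes without a symbol gave 1144 of the higher and 533 of the lower calls, so most called genes with a symbol were lower. The higher share over all genes was 48.9% of calls. It was 38.7% with a pseudocount of 0.1, 41.56% with the filter of 5 FPKM, and 64.2% after median-ratio scaling, which moved the median of all genes from -0.03 to 0.17. The count moved by over 1.5 times without any single library. It was 12238 without 18M animal 2, which kept 99.9% of the 4051, and fell to 839 without 4Y animal 1 and to 626 with only the 6 libraries compared in the fit. Of the 40 named genes called in this comparison, 30 lost their call under at least 1 alternative. Calls of 23 to 29 of the 40 ended without 18M animal 1 or 3 or any 4Y animal (adjusted p up to 0.153), of 9 to 11 without a 6M animal (up to 0.0772) and of 0 without 18M animal 2. ID4, P3H3, CRABP2, INAFM1, RPS15 and MRC1 were among the 10 that stayed called in all alternatives. MEIOC, OST4, MRPS33 and Y_RNA also stayed called in every leave-out (adjusted p up to 0.00316). Their calls rest on values of 0 in all 18M libraries, which can be failed estimates. Camera called 9 lists, 5 without 18M animal 3 and 12 without 18M animal 2.

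**Figure D3:**
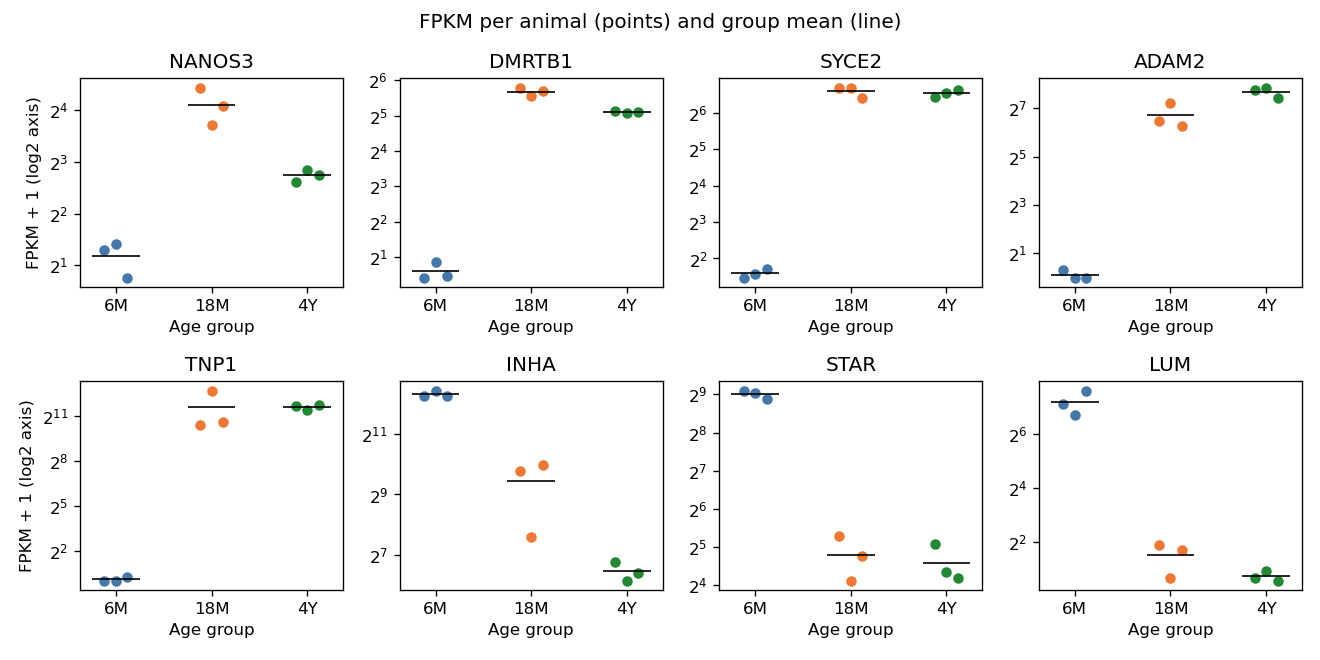
FPKM + 1 on a log2 axis (y) by age (x) for 8 named genes; points are animals and lines are means of 3. STAR is at 512 at 6M, 26.7 at 18M and 23.1 at 4Y, and INHA at 5107, 696 and 86.7 FPKM.

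**Figure D4:**
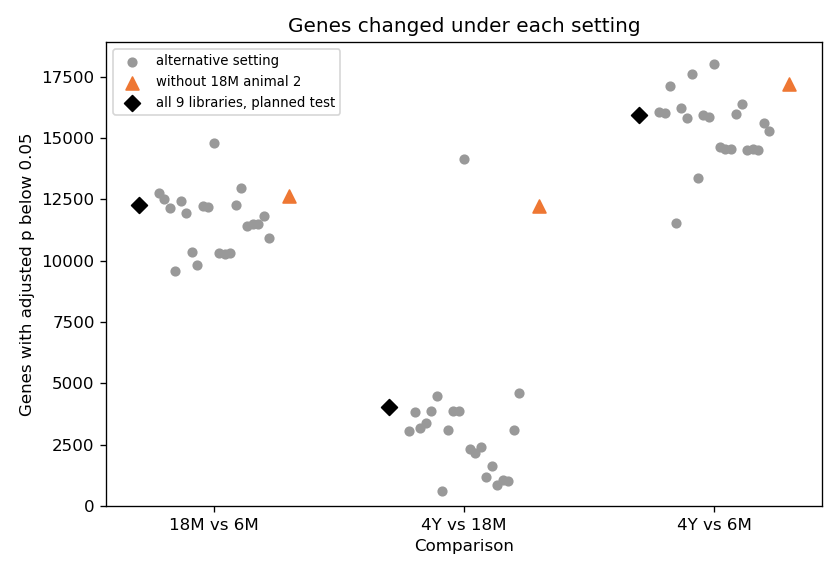
Number of genes with adjusted p below 0.05 (y axis) in each comparison (x axis) for the planned test (diamond), each alternative (grey points) and the fit without 18M animal 2 (triangle). The 4Y against 18M count moves from 4051 to 12238 without that animal.

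The 18M libraries enter both steps with opposite signs. Of the genes higher at 18M, 1088 were higher again at 4Y, against 792 for independent lists of the same sizes and 0 in simulations of unchanged groups, and 713 were lower, against 828 and a simulated mean of 15.02. Of those lower at 18M, 359 were lower again (345 and 0) and 70 higher (330 and 15). Leaving out single libraries moved these counts widely, the first from 150 without 4Y animal 1 to 3688 without 18M animal 2. The covariance of the log2 fold changes of both steps over the 21646 genes was 0.522, against -0.171 over 50 simulations of unchanged groups, a difference of 0.693. The shared libraries push toward opposite directions, as this simulated value shows. The simulated 0 for calls in the same direction therefore follows from the design when no gene changes. It does not tell how often genes that did change in the first step would change again. The counts for independent lists leave the shared libraries out of account. With 3 libraries the 18M group could not be split into parts of at least 2.

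Between 6M and 4Y, 15933 genes changed, 9993 higher and 5940 lower. The higher share was 62.7% of calls and 43.9% after quantile normalization. TNP1 again had the largest rise (log2 fold change 11.52 ± 0.50), and CMTM2 rose from 0.857 ± 0.588 to 1293 ± 39.3 FPKM (9.50 ± 0.30). TMSB4X, listed at 0 at 6M, was at 1350, 1165 and 960 FPKM. The largest falls were of CHGA (-8.15 ± 0.59), CRABP2 (-7.50 ± 0.56) and PLA2G1B (-7.27 ± 0.91). All tested genes of the meiosis, round spermatid, elongating spermatid and axoneme lists rose, 13 of 14 Leydig and 25 of 31 matrix genes fell, and so did 38 of 38 ribosomal protein genes. Of 20 Sertoli genes 13 fell and 4 rose, and of 12 endothelial genes 9 fell and 2 rose. Of 15 leukocyte genes 8 fell and 3 rose, and of 14 immediate early and heat shock genes 8 fell and 1 rose. Camera called 17 lists, 0 with an estimated correlation (adjusted p = 0.37 or higher). The myoid (adjusted p = 0.107) and the immediate early and heat shock list (0.0613) lost their calls without 6M animal 3 among other alternatives, the cell cycle list without 18M animal 2 (0.0554) among others, and the barrier list after quantile normalization (0.0826). Calls were gained by the leukocyte list without 6M animal 1 (0.0262) or 4Y animal 2 (0.0363), the hypoxia list without 18M animal 2 (0.0466), and the differentiating list with no filter (0.0389) and without 6M animal 2 (0.0431). Of the 17 lists fry did not call the Sertoli (adjusted p = 0.208), myoid (0.14), barrier (0.0688) and immediate early and heat shock (0.214) lists, and it called the differentiating list (4e-05). Its mixed test called each of these lists (adjusted p up to 0.00338).

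At the level of isoforms, 28003 of 63906 changed between 6M and 18M, 19237 higher and 8766 lower, and 14008 between 18M and 4Y, 7528 higher and 6480 lower. The higher share was 68.7% for 18M against 6M but 43.0% after quantile normalization, and 53.7% for 4Y against 18M but 72.4% after median-ratio scaling, 44.85% with a pseudocount of 0.1 and 44.18% with the filter of 5 FPKM. Without 18M animal 2 the 4Y against 18M count was 28636, and without 4Y animal 1 it was 7792. Isoforms of genes added to the annotation were higher at 18M in 36.4% of 8012 and at 4Y over 18M in 15.6%, against 29.6% and 13.5% of the 15443 Ensembl transcripts.

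Many genes were called for unequal change of their isoforms on the log2(FPKM + 1) scale. For ACSL6, a fatty acid activating enzyme, 1 isoform (t15) held 86.1% ± 2.78 of the FPKM of the gene's tested isoforms at 6M. It is listed at 0 in all 18M libraries, while another (t13) is listed at 0 at 6M and held 40.02% ± 8.15 at 18M. The shares of the genes that follow are likewise of the tested isoforms. In CDC34, a ubiquitin conjugating enzyme, the leading isoform (t7) held 49.7% ± 3.06 at 6M and 27.3% ± 13.0 at 18M, where an Ensembl transcript listed at 0 at 6M held 50.7% ± 15.1. For the kinesin gene KIF19 an added isoform (t7) held 93.8% ± 2.04 at 18M (279 ± 90.0 FPKM), but the isoform that led at 6M was at 0.767 ± 0.684 FPKM, so the 6M shares rest on low values. Between 18M and 4Y the leading isoform of ARFRP1 passed from t5 (50.8% ± 16.5 at 18M, 5.31% ± 1.33 at 4Y) to t7, listed at 0 at 18M and at 51.8% ± 3.09 at 4Y. SPHK2, a sphingosine kinase, went from t12 (64.4% ± 2.99 at 18M, 0.367% ± 0.635 at 4Y) to t5 (4.40% ± 1.14 and 30.5% ± 4.76). In TCFL5, a transcription factor of spermatocytes, t1 held 49.5% ± 1.16 at 18M and is listed at 0 at 4Y, while its Ensembl transcript held 48.1% ± 2.12 and 47.4% ± 1.89. Values of 0 throughout an age can be failed estimates. Adjusted p-values of the own-spread test were 1.5e-05 to 0.000163 for these 6 genes.

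The planned diffSplice test called 6423 of 12670 genes for 18M against 6M, with 3359 switches, and 5300 for 4Y against 18M, with 2732 switches. Of these switches, 2848 and 2709 were in genes whose tested isoforms together reached a mean of 1 FPKM at both ages. With each isoform's own spread, an alternative chosen after seeing the data, the counts were 6402 with 3280 switches and 5164 with 2600 switches, and 5618 and 4328 genes were called by both tests. Another test, on isoform shares, called fewer genes and is given in the closing section. The estimates of single isoforms from short reads are uncertain where isoforms share most of their sequence.

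The authors' deposited table for 18M against 6M holds 66580 isoforms, with 19876 called up and 8218 called down. The authors' deposited table for 4Y against 18M holds 75066, with 5491 up and 6731 down. In the authors' deposited tables the calls are those with an adjusted p below 0.05 and an absolute log2 fold change above 1. Of 25499 isoforms called here for 18M against 6M and present in the authors' deposited table, 84.4% were called there in the same direction and 0 in the opposite one. For 4Y against 18M this was 60.3% of 13273, with 3 in the opposite direction. In turn, of the isoforms in both tables that the authors called, 89.3% of 24111 and 80.5% of 9944 were also called here in the same direction. The calls here had no fold threshold. Both use the same libraries, so this is a description and not independent evidence.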

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

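The arcsine test of isoform shares, the own-spread test and the leave-out of 18M animal 2 from the range of list medians were chosen after seeing the data. So were the counts of called list members without 18M animal 2, which are given for no other leave-out. The leave-outs themselves and the other alternatives were planned. The counts of changed genes for 18M against 6M and 4Y against 6M stayed within 1.5 times under all alternatives run; each leave-out range below gives the lowest and the highest value. In 1831 of 2077 checks of a named gene and 1037 of 1134 of a list, direction and side of the threshold were kept. Count tests were not run because the values are FPKM. Where no value is named as the cause, the cause was not tested.

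Genes changed for 4Y against 18M numbered 839 (without 4Y animal 1) to 12238 (without 18M animal 2) over the leave-outs. They numbered 626 with 6 libraries in the fit and 14131 with sample weights. The fit of 6 libraries kept 15.18% of the planned calls here, but 83.82% for 18M against 6M and 99.81% for 4Y against 6M. Those comparisons had 12259 and 15933 calls, against 4051 here, so the kept shares cannot tell whether fewer samples account for the fall. Without 6M animal 1, 2 or 3, none of them part of this comparison, 56.9%, 53% and 58.78% of the planned calls were kept. The planned fit shares a single spread over the ages although the 18M animals were less alike, so its standard errors for 4Y against 18M may be too small. Isoforms changed for 4Y against 18M ranged over the leave-outs from 7792 to 28636, with 6597 for 6 libraries in the fit and 21169 with sample weights. With the filter of 5 FPKM, which tests fewer isoforms, isoforms changed were 15665 for 18M against 6M and 8187 for 4Y against 18M, usage 2951 and 2817, and switches 1532 and 1433. The arcsine test gave usage in 3983 genes and 2174 switches for 18M against 6M, and 3225 and 1746 for 4Y against 18M; it recovered 0 simulated genes. The own-spread test gave 6402 and 3280, and 5164 and 2600.

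Overlap of both steps over the leave-outs was 150 to 3688 genes higher then higher, 178 to 1881 higher then lower, 12 to 219 lower then higher and 47 to 1884 lower then lower, the lowest without 4Y animal 1 and the highest without 18M animal 2. With a pseudocount of 0.1, higher then higher was 642. With median-ratio scaling higher then lower was 320 and lower then higher 176. With quantile normalization these were 449 and 236, and lower then lower was 713. With a log2 fold of at least 1 they were 338 and 30. Camera called 0, 0 and 0 lists with an estimated correlation in the 3 comparisons, and 5 (without 18M animal 3) to 12 (without 18M animal 2) lists for 4Y against 18M over the leave-outs. The share called in the authors' deposited table in the same direction was 86.66% with a pseudocount of 0.1 and 87.07% with a log2 fold of at least 1 for 18M against 6M, and 73.12% and 61.90% for 4Y against 18M.

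Direction reversed, without a call on either side except for HBA, in these cases. PCNA for 4Y against 18M was at 0.191 with median-ratio scaling and between -0.236 and 0.057 over the leave-outs. DMRT1 was at 0.051 with the highest isoform per gene. HBA for 18M against 6M was at -0.110 with quantile normalization. Camera's direction reversed for undifferentiated spermatogonia, 18M against 6M (median 0.676 with the filter of 5 FPKM, -0.004 to 0.808 over the leave-outs), and for the cell cycle list, 4Y against 18M (-0.126 to 0.133 over the leave-outs).

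The replicate numbers do not pair the animals. Deviations of same-numbered libraries correlated at -0.071 to 0.064 and of others at -0.085 to 0.072, and 3 of 9 libraries correlated best with their own number. With the number as a replicate block, genes changed were 11816 for 18M against 6M, 3095 for 4Y against 18M and 15609 for 4Y against 6M, called lists 15, 11 and 17, isoforms changed 26637 and 11994, usage 6331 and 5162, switches 3327 and 2677, and overlaps 774, 524, 47 and 300. Depth is not stated, so a low FPKM has no counting interval here.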

Other observations

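All tests of the 3 patterns below, and the pathway tests, were chosen after the results were seen; the counts over other splits of the libraries were planned. Pathway membership as given in the deposited table was tested with limma's camera for 149 KEGG pathways with at least 15 tested genes. At 18M against 6M 44 were called lower and 0 higher, and 0 with an estimated correlation (the lowest adjusted p was 0.664). Of 203 genes of the Ribosome pathway 115 fell and 37 rose (median log2 fold change -0.99). Of 137 Lysosome genes 51 fell and 31 rose (median -0.49; camera adjusted p = 0.00011), and of 16 Steroid biosynthesis genes 9 fell and 2 rose (median -1.36; camera adjusted p = 0.0036). At 4Y against 18M 2 pathways were called, both lower and 0 with an estimated correlation (adjusted p = 0.967). These were Ribosome, with 71 of 203 lower and 15 higher, and Oxidative phosphorylation, with 29 of 128 lower and 1 higher (median -0.47; camera adjusted p = 0.000123).

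The first pattern is that 18M animal 2 lies nearer the 4Y animals than the other 18M animals in gene values. A further library of the 4Y group under an 18M label is argued against by isoform shares. Over 8714 genes the share of a gene's FPKM that would have to be reassigned between isoforms was at least 24.47% between 18M animal 2 and a 4Y animal, but 14.3% to 15.2% within 4Y, and 21.7% and 24.6% to 18M animals 3 and 1; a 4Y animal handled with the 18M libraries stays open. A swap is argued against by the 4Y animals, whose lowest r among themselves was 0.9719, against at most 0.837 with 18M animals 1 and 3. A cell makeup nearer that of 4Y stays open; earlier puberty and the part of the testis sampled cannot be told apart because the labels record neither, and the deviation of animal 2 from 18M animals 1 and 3 along the difference of 4Y from 6M (r = 0.739 across genes) restates the pattern.

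The second pattern is that isoform shares differ between 18M and 4Y, less so for 18M animal 2, which lay about as near to a 4Y animal as to 18M animal 1. If cell makeup alone were the cause, isoforms at 0 in 18M animals 1 and 3 and at 5 FPKM or more in all 4Y animals might mostly be above 0 in 18M animal 2. Of 591 such isoforms 51.4% were also at 0 there (exact 95% binomial interval 47.3% to 55.5%), too near to 50% to decide, and 41.1% were at 1 FPKM or more. Holding out 18M animals 1 and 3 in its place gave 73.6% and 80.0% at 0. The number of isoforms at 0 in one trio of libraries and at 5 FPKM or more in the other was 443 for the split by age and at most 13 for the other 9 splits, and handling or quantification that differed between the ages cannot be told apart from age because each age may have been handled as 1 group.

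The third pattern is that the Leydig and matrix lists were lower at 18M than at 6M; the endothelial list was lower as well (camera adjusted p = 0.00193, and called under all leave-outs and both other scalings), the Sertoli list also, until quantile normalization (0.241), the myoid list was called in 4 leave-outs only, and the leukocyte list was not called (0.172). The medians of the Leydig and matrix lists were -1.987 and -2.057 with median-ratio scaling and -2.24 and -2.255 with quantile normalization. These scalings also moved the median of all genes down, from 0.491 to 0.281 and -0.175. They pushed both lists away from 0, so they cannot decide whether the authors' FPKM scaling was the whole cause. Leaving out a library moved a median by at most 0.533. A lower share of somatic cells alone, as germ cells expand, cannot be told apart from changes within these cells. The medians of 6 somatic lists ranged from -1.80 (matrix) to -0.003 (myoid; permutation p = 0.014, and 0.0131 for a range of 1.78 without 18M animal 2), but myoid members went both ways, genes of a list are correlated and cell types can be diluted unequally.

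With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each case 1 of the 10, the split by age, gave as many calls. Every other split puts libraries of both ages in each group, so a difference between the ages enlarges the spread within groups. Few calls in the other splits therefore follow from the design and do not measure chance. For genes changed the split by age gave 12259 calls and the highest other split 1 for 18M against 6M, 4051 and 20 for 4Y against 18M, and 15933 and 0 for 4Y against 6M. For isoforms changed it gave 28003 against 4, and 14008 against 115. For usage it gave 6423 against 51, and 5300 against 149.

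Isoforms listed at 0 in all libraries of one age and at 5 FPKM or more in all of the next numbered 1079 from 6M to 18M and 304 from 18M to 4Y, and in the reverse sense 115 and 139. For genes these numbers were 234, 21, 6 and 3.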
